A study of Mus musculus with 2 samples.

How the data were processed

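The data were 2 droplet-based single-cell RNA libraries of FACS-isolated mouse satellite cells, 1 per sorted fraction, with the groups taken from the sample labels. The deposited matrices held raw UMI counts per gene and barcode for all barcodes, not only cells, over 32286 features, and per the file headers they were made with Cell Ranger version 4. The submitters' processing notes name Cell Ranger and Seurat and the genome build mm10. The annotation release, the counting settings and the sequence of the added reporter feature are not given in the sources used here. Free RNA, barcode calling and reads that map to several genes act on these counts before any step described below.

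Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept: 604 of 647 barcodes over 1000 UMIs in the GFP+ library and 2683 of 3076 in the GFP− library, of which 43 and 388 barcodes exceeded the mitochondrial limit. Doublets were called per library with scrublet as implemented in scanpy 1.11.5 at an expected rate of 0.08. It called 5 GFP+ cells (0.828%) and 2 GFP− cells (0.075%), the latter far below the 2.15% that 0.8% per 1000 cells would give, so doublets in the GFP− library were in effect not removed. Empty droplets, used to gauge free RNA, were barcodes with 1 to 100 UMIs. Both libraries were clustered together, with counts scaled to 10000 and log transformed, 2000 variable genes (without Pax3, Six2, the reporter, sex-linked, mitochondrial, ribosomal protein and haemoglobin genes), 30 principal components, 15 neighbours and Leiden resolution 0.6, and without integration because library and group coincide. A cluster counted as myogenic where its strongest non-myogenic marker class stood under 2 log2 units above the other clusters, a limit chosen after the data were seen. The clusters outside the class were the macrophage-like, mural-like and glial-like ones, which held 12.5%, 1.00% and 0% of GFP+ cells and 2.13%, 4.70% and 0.671% of GFP− cells. Cell types were named from fixed marker lists, and the names are rebuilt here, not the authors'.

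UMIs were summed per library and scaled to the library's total of the same cells (CPM), a unit computed here from the deposited counts. The ratio of the GFP+ to the GFP− value was given with the exact conditional (Clopper-Pearson) interval, and shares of cells with exact binomial intervals. A gene with 0 UMIs in 1 library was set against a floor of 3 counts over the group. Genes passed a size rule of at least 20 CPM in at least 1 library, a ratio of at least 2 and a CPM at least 0.5 times that of the empty droplets. The named genes were the Pax-Six-Eya network and the 4 myogenic factors, the 12 highest and 12 lowest ratios past this rule (7 existed for the lowest) without mitochondrial, ribosomal protein, haemoglobin, Gm-numbered and Rik-named genes, and up to 4 members per list with the largest log2 ratio. A part of the rule that needed 100 cells of each library per cluster named none, since 0 clusters met it. List medians used members with a mean CPM of at least 10, and random lists were matched on expression in 20 bins. Shares of cells with a UMI were compared after thinning each cell to 5000 UMIs, which left out 59 GFP+ and 135 GFP− myogenic cells. Gene positions and transcript lengths came from GENCODE M21 on the same build, which matched 32158 of the 32286 features.

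The calculations were tested on simulated counts drawn for the comparison of GFP+ with GFP− myogenic cells, from the pooled mean of both libraries and their sizes, for 32286 genes, with 50 genes changed at each of 4 fold sizes. Median recovered ratios were 1.51, 2.49, 4.00 and 0.398 for simulated folds of 1.5, 2.5, 4 and 0.4; 0 of the 50 genes at 1.5-fold and all 50 at each other size passed the size rule, and 0 of 7556 unchanged genes did. Intervals covered the simulated value for 92.0% to 96.0% of the changed genes per size and 95.7% of the unchanged genes. The sums were drawn with Poisson counting error alone, so such coverage was bound to follow and leaves out variation between cells. The simulated counts also stood in for the empty droplets, so that part of the size rule was not tested. In simulated counts with the Notch list raised 1.5-fold its median was 0.62, and the largest of the other lists was 0.030. In counts with an added length trend the slope of −0.20 became −0.00020 after its removal. In 1000 simulated shallow and 1000 deep cells of 1 composition, thinning brought Pax7 shares of 74.0% and 95.7% to 56.4% and 56.3%. Pax3 shares of 6.40% and 13.5% came to 5.10% and 2.90% in the same run, and over 20 repeats to means of 3.98% (SD 0.455) and 4.05% (SD 0.600), where the composition gives 4.19%. The repeats were added after the single run was seen. Myog, near 100% before and after, could not show a correction. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9 were used, and edgeR 4.0.16 in R 4.3.3 gave TMM factors as an alternative scaling. No test across samples could be run with 1 library per group. Choices of cells, clustering resolution, scaling, free RNA, cell weighting and thresholds were varied one at a time, and 5 further alternatives were added after seeing the data.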

Results

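Satellite cells are the resident stem cells of skeletal muscle, and PAX3 is a transcription factor that a subset of them expresses. Cells were sorted from the biceps and recto femoris muscles of Pax3GFP/+ mice 5 days after injury, in which GFP reports the Pax3 locus, and split into a GFP+ (PAX3+) and a GFP− (PAX3−) fraction. Which biceps is meant and whether both muscles entered each library are not given in the sources used here. Each fraction gave 1 droplet-based 3′ single-cell RNA library from 20000 loaded cells, so there were 2 libraries and no replicates. All intervals are 95% intervals that cover counting error only, no statistical test between the fractions was possible, and every difference is a difference between these libraries. The GFP+ library held 13928952 UMIs (unique molecular identifiers, 1 per captured transcript) over 718416 barcodes, and the GFP− library 49709323 UMIs over 1361552 barcodes. After filtering, 599 GFP+ cells with a median of 18561 UMIs and 2681 GFP− cells with a median of 14654 UMIs remained. Their median mitochondrial shares of UMIs were 2.49% and 4.46%. Myogenic cells made up 86.5% of the GFP+ cells (518 cells) and 92.5% of the GFP− cells (2480 cells), and held 10472610 and 42140833 UMIs.

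The first comparison checked the sort by Pax3 itself. Since GFP reports the Pax3 locus, higher Pax3 in GFP+ cells is what the sort selects for and is no independent result. Pax3 (ENSMUSG00000004872, chromosome 1, 78101267 to 78197134, minus strand, GRCm38/mm10) was 4.32-fold higher in GFP+ than in GFP− myogenic cells (interval 3.58 to 5.22), at 22.2 against 5.15 CPM, summed UMIs scaled to the library's total. The ratio lay above 1 in each of the 8 myogenic clusters, with its counting interval above 1 in all 8. A reporter feature of the deposited matrices, whose name joins a histone-GFP fusion to TVA and B19G, elements of viral tracing, had 567 UMIs in GFP+ myogenic cells (54.1 CPM) and 0 in GFP− myogenic cells, a ratio of at least 761-fold against a floor of 3 counts over the group. Which part of that sequence was counted is not given in the sources used here. After each cell was thinned to 5000 UMIs, Pax3 was detected in 12.4% of 459 GFP+ myogenic cells (interval 9.54 to 15.8) and 2.94% of 2345 GFP− myogenic cells (2.30 to 3.71). Without thinning the shares were 30.9% and 7.42%. Among macrophage-like cells at the same thinned depth Pax3 was detected in 0 of 68 GFP+ and 0 of 44 GFP− cells. At a floor of 3 counts over the group this allows up to 4.41% and 6.82%, and the exact binomial upper limits were 5.28% and 8.04%. Median depths before thinning were 19114 and 14996 UMIs in GFP+ and GFP− myogenic cells, and 13571 and 8086 in macrophage-like cells. The GFP− share thus lay below the limit that these few macrophage-like cells allow. Pax3 in the GFP− library was not at 1 level across cell types, however. It stood at 9.66 CPM in cluster 2 (6.52 to 13.8) and at 0 UMIs in the 126 mural-like cells, which allows up to 2.34 CPM at the same floor (Poisson limit 2.88). The GFP− macrophage-like cells, at 3.13 CPM from 2 UMIs (0.379 to 11.3), overlapped the myogenic level. GFP− cluster 8 had 0 UMIs, which allows up to 15.8 CPM at that floor (Poisson limit 19.5), and empty droplets of that library held 3.57 CPM.

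**Figure D1:**
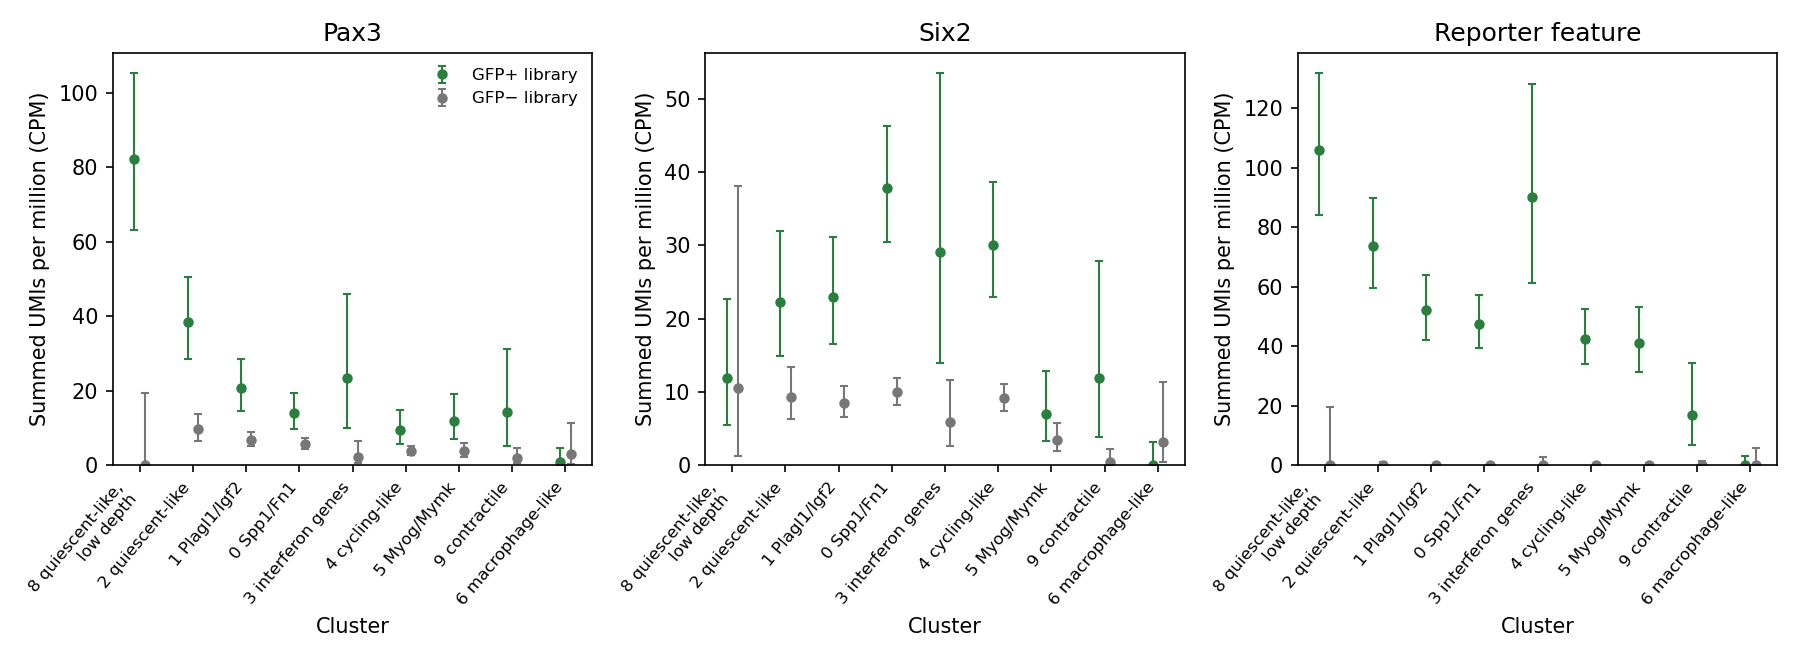
CPM of Pax3, Six2 and the reporter feature (vertical axes) in the 8 myogenic clusters and the macrophage-like cluster (horizontal axes) in the GFP+ (green) and GFP− (grey) libraries; points are CPM of summed UMIs and bars are exact 95% Poisson intervals. Pax3 was highest in GFP+ cluster 8 (82.2 CPM), Six2 was highest in GFP+ cluster 0 (37.7 CPM), and the reporter feature had 0 UMIs in each GFP− cluster shown.

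The second comparison concerned Six2, a homeobox transcription factor named with PAX3 in the series title, and the rest of the Pax-Six-Eya network, transcription factors and cofactors of myogenesis. Six2 (ENSMUSG00000024134, chromosome 17, 85684277 to 85688274, minus strand) was 3.04-fold higher in GFP+ myogenic cells (interval 2.57 to 3.58), at 24.4 against 8.04 CPM. Its ratio exceeded 1 in all 7 myogenic clusters with enough UMIs to compare, and the interval lay above 1 in 5 of them. Other network members did not follow it: Six4 was at 0.782-fold (0.698 to 0.874), Eya1 at 0.772-fold (0.637 to 0.931) and Eya4 at 0.782-fold (0.672 to 0.906) of the GFP− level. Eya2, Eya3 and Six5 were at 0.781-fold, 0.911-fold and 1.17-fold with intervals that included 1, and Dach1 (5 and 12 UMIs) and Dach2 (0 and 1) had too few UMIs to compare. Pax7, the paralogue that marks satellite cells, was 1.42-fold higher in GFP+ cells when all clusters were pooled (1.35 to 1.49). At 5000 UMIs Six2 was detected in 55 of 459 GFP+ myogenic cells (interval 9.16% to 15.3%) and 94 of 2345 GFP− myogenic cells (4.01%, 3.25 to 4.88), and without thinning in 29.3% and 11.7%. At the same thinned depth it was detected in 0 of 68 GFP+ and 1 of 44 GFP− macrophage-like cells, so the GFP− share was not distinguishable from that background by cell shares. The GFP− macrophage-like cells also carried myogenic RNA, with 145 UMIs of Myog and 40 of Myf5 against 5 and 0 in GFP+. As a background they were therefore not clean. By summed UMIs it differed between GFP− cell types, from 9.95 CPM in cluster 0 (8.22 to 11.9) to 0.391 in the contractile cluster 9 (0.0099 to 2.18). Over all GFP− myogenic cells Six2 was not above the 8.62 CPM of that library's empty droplets, which by itself does not show that it was free RNA. Lyz2 and Cd74, leading genes of the macrophage-like cluster, stood at 2.71 and 1.31 CPM in these cells against 513 and 91.5 in those droplets. Such low carry-over argues against free RNA as the main source of their Six2. Whether Six2 also differed outside the myogenic cells could not be told from 0 and 2 UMIs in macrophage-like and 1 and 6 UMIs in mural-like cells of GFP+ and GFP−.

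The third comparison asked how the fractions were distributed over myogenic states. Joint clustering gave 11 clusters, of which 8 were myogenic. Cluster 8, a quiescent satellite cell-like cluster with Erfe, Chrdl2, Clmn and Atf3 among its leading genes, held 22.6% of GFP+ (interval 19.1 to 26.4) and 1.94% of GFP− myogenic cells (1.43 to 2.56), 11.7 times the share (25.1 times, from 116 and 22 cells, under order-of-magnitude cell calling). Its median depth was low, 6322 UMIs in GFP+ and 3592 in GFP− cells, and 1 of its 10 leading genes, Chrdl2, was a marker of the quiescent class. Pax7 was the highest of the clusters there (637 CPM in GFP+ and 591 in GFP−), with 1 and 0 UMIs of the proliferation marker Mki67. Myod1, a determination factor, stood at 158 and 227 CPM, against 37.6 and 34.1 in cluster 2. The stress gene Fos, at 1785 and 2510 CPM, was the highest of the myogenic clusters. These genes did not settle a quiescent state. The leading genes of cluster 8 had a median log2 ratio of 0.81 outside it. Outside it, however, Erfe, Chrdl2, Atf3, Hmcn2 and Prelp stood under 0.5 times the level of GFP+ empty droplets, so they did not pass the size rule there. When the 1053 genes that differed by over 1.5-fold between the libraries were left out of the clustering, the matching cluster still held 23.0% and 2.33%, a ratio of 9.85. Its markers then placed it in the endothelial class, so the class given to it depended on the clustering. With 1 library per group, a cluster mostly from 1 library may reflect that library and not a cell type. A second quiescent-like cluster, cluster 2, with Chodl and Tenm4 among its leading genes, held 16.0% of GFP+ and 11.7% of GFP− myogenic cells. The cycling-like cluster 4 held 11.2% (8.61 to 14.2) and 17.7% (16.2 to 19.3), and the differentiating myocyte-like clusters 5 and 9 together held 14.3% (11.4 to 17.6) and 14.9% (13.5 to 16.3), shares that overlapped. Cluster 9 alone, led by contractile genes, held 2.90% of GFP+ (15 cells, 1.63 to 4.73) and 4.31% of GFP− myogenic cells (107 cells, 3.55 to 5.19). Clusters 0, 1 and 3, led by Spp1 and Fn1, by Plagl1 and Igf2 and by interferon genes, held 35.9% of GFP+ and 53.8% of GFP− myogenic cells.

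**Figure D2:**
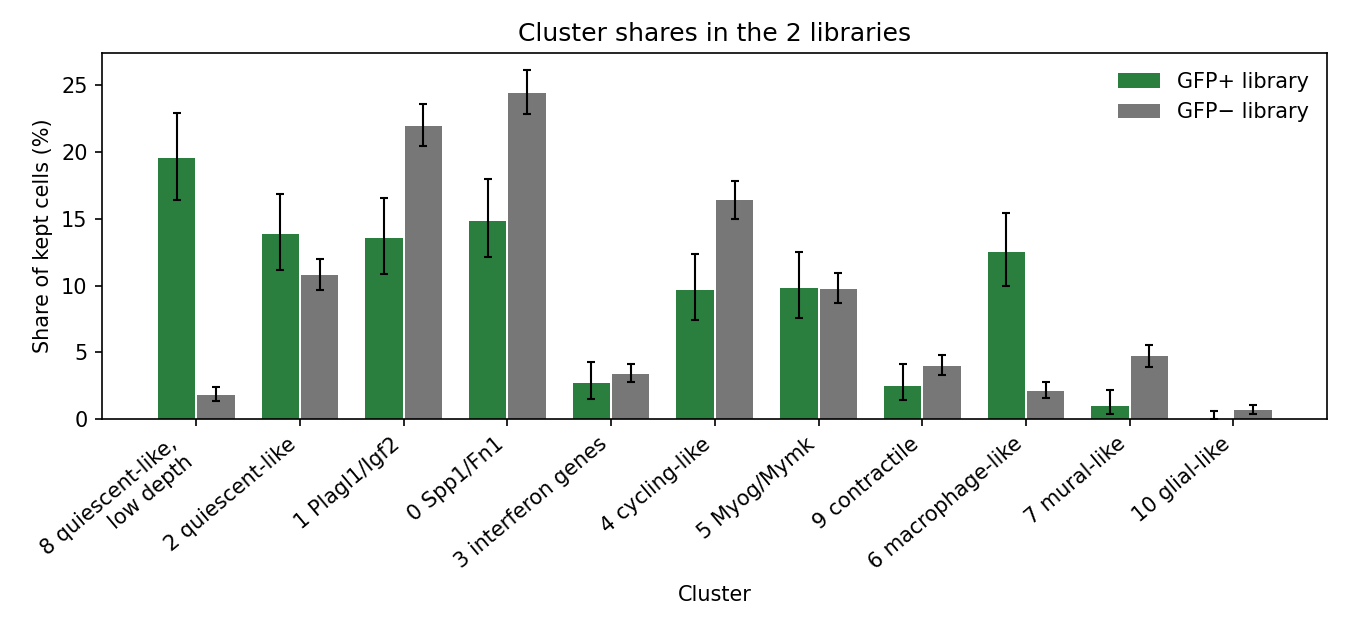
Share of kept cells in each cluster in the GFP+ (green) and GFP− (grey) libraries; bars are shares in percent and error bars are exact 95% binomial intervals. Cluster 8 held 19.5% of GFP+ and 1.79% of GFP− cells, and the macrophage-like cluster 6 held 12.5% and 2.13%.

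Cell cycle lists were lower in GFP+ myogenic cells, Myf5 and Pax7 were higher, and Myod1 did not differ beyond counting error when all clusters were pooled. Mki67, a proliferation marker, was at 0.518-fold of its GFP− level (0.467 to 0.573) and detected in 7.41% of GFP+ (5.18 to 10.2) and 12.7% of GFP− cells (11.4 to 14.1) at 5000 UMIs, with intervals that overlapped without cluster 8 (8.88%, 6.23 to 12.2, against 12.8%, 11.4 to 14.2). The macrophage-like cells had 11.8% and 11.4%, but whether they cycle was not tested, so they give no background for this gene. Of the 3288 GFP− myogenic UMIs of Mki67, 3077 lay in the cycling-like cluster 4, which Mki67 helps to define. It stood there at 280 CPM (270 to 290), against 6.66 in GFP− cluster 0 (5.26 to 8.33). Without thinning it was detected in 13.5% and 19.2% of myogenic cells. The share of UMIs in the G2/M list was 0.217% in GFP+ (0.214 to 0.220) and 0.296% in GFP− myogenic cells (0.294 to 0.297), and in the S phase list 0.102% and 0.123%. Within the cycling-like cluster 4 the S phase share was not lower in GFP+, at 0.296% (0.289 to 0.304) against 0.291% (0.288 to 0.294). The G2/M share there was 0.763% and 0.854%. Cells with at least 3 G2/M UMIs made up 76.0% and 80.6% of myogenic cells, while cluster 4 held 11.2% and 17.7%, so this threshold did not separate cycling cells. Macrophage-like cells had 61.8% and 65.9%. Myf5, an early myogenic determination factor, was 1.55-fold higher (1.49 to 1.62) and detected in 62.5% of GFP+ and 52.6% of GFP− cells at 5000 UMIs, against 0 of 68 and 3 of 44 macrophage-like cells, and in 76.4% and 74.5% without thinning. Pax7 was detected in 61.0% and 49.6% at 5000 UMIs, against 1 of 68 and 0 of 44 macrophage-like cells, and in 81.7% and 73.2% without thinning. Cluster 8 carried part of this: without it Pax7 was at 1.21-fold (1.14 to 1.28) and Myf5 at 1.47-fold (1.41 to 1.53), and their shares, 54.0% against 49.5% and 59.5% against 52.6%, had intervals that overlapped. Myod1, a determination factor, was at 1.03-fold (0.966 to 1.10) over all clusters. Single clusters went both ways, such as cluster 0 at 0.700-fold (0.553 to 0.877) and cluster 4 at 1.48-fold (1.30 to 1.67). Myod1 was detected in 22.2% and 23.0% (197 of 518 and 925 of 2480 cells without thinning; macrophage-like cells 0 of 68 and 2 of 44). Myog, a differentiation factor, was 1.21-fold higher in summed UMIs (1.19 to 1.24) but detected in fewer GFP+ than GFP− cells, 18.1% and 23.0% (24.3% and 29.2% without thinning; macrophage-like cells 1 of 68 and 2 of 44), and no order was read from these opposed values.

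Across single genes, 80 were at least 2-fold higher in GFP+ myogenic cells and 10 at least 2-fold lower, among 5785 genes reaching 20 CPM in at least 1 library. Among the highest ratios were those of H2-Q4, a class I histocompatibility gene (6.40-fold), Erfe, which encodes the hormone erythroferrone (5.24-fold), Atf3, a stress-induced transcription factor (4.82-fold), Pax3, Rpgrip1 (4.07-fold), Polr2l, an RNA polymerase subunit (3.90-fold), Hmcn2 (3.56-fold), Lmod2 (3.29-fold), Bloc1s1 (3.28-fold), F2r, a thrombin receptor (3.24-fold), and Prelp (3.15-fold). Pax3 is the gene whose locus the sort reports. The H2-Q4 value is uncertain because class I genes share near-identical sequence that counting can split. Erfe, Atf3, Hmcn2 and Prelp were among the genes that define cluster 8. Among the lowest ratios were those of Cxcl10, a chemokine (0.176-fold), and of Tnnc2 (0.261-fold) and Tnnt3 (0.371-fold), troponin genes of contractile muscle. Others were Cenpe, a kinetochore motor of mitosis (0.437-fold), Ifitm1, an interferon-induced membrane protein (0.475-fold), and Mef2c, a myogenic transcription factor (0.479-fold). Empty droplets held more Cxcl10, Tnnc2 and Tnnt3 than the cells in both libraries (57.3 CPM of Tnnc2 in GFP− against 31.8). The contractile cluster 9, with 15 GFP+ and 107 GFP− cells, held 2602 of the 3719 GFP− myogenic UMIs of Tnnt3 and 648 of the 1341 of Tnnc2. In GFP+ it held 105 of 343 and 3 of 87. The Tnnt3 ratio thus rested largely on that cluster. Without cluster 8 the counts of higher and lower genes were 38 and 8, of which 36 and 7 were shared with the full set. Erfe then stood at 1.87-fold, Atf3 at 2.10-fold, Lmod2 at 1.39-fold, F2r at 1.78-fold and H2-Q4 at 3.29-fold, and the interval of Prelp included 1 (0.968 to 1.59). Erfe, Atf3, H2-Q4 and Prelp were then under 0.5 times the level of GFP+ empty droplets (18.2 against 73.7 CPM for Erfe), so they no longer passed the size rule. This does not show that what remained was free RNA. Lyz2, a macrophage marker, was at 6.11 CPM in GFP+ myogenic cells against 2196 in empty droplets, and Cd74 at 3.53 against 1169. These values argue against free RNA as the main source of the remaining Erfe, Atf3, H2-Q4 and Prelp. Without cluster 8 Polr2l was at 3.94-fold and Bloc1s1 at 3.31-fold. Polr2l, Rpgrip1 and Bloc1s1 were also higher in GFP+ macrophage-like cells, at 5.16-fold (2.84 to 10.3), 8.61-fold (2.20 to 74.1) and 2.52-fold (1.37 to 5.01), so their ratios were not particular to myogenic cells. Without cluster 8, Pax3 stood at 3.40-fold (2.77 to 4.18) and Six2 at 3.16-fold (2.67 to 3.74).

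**Figure D3:**
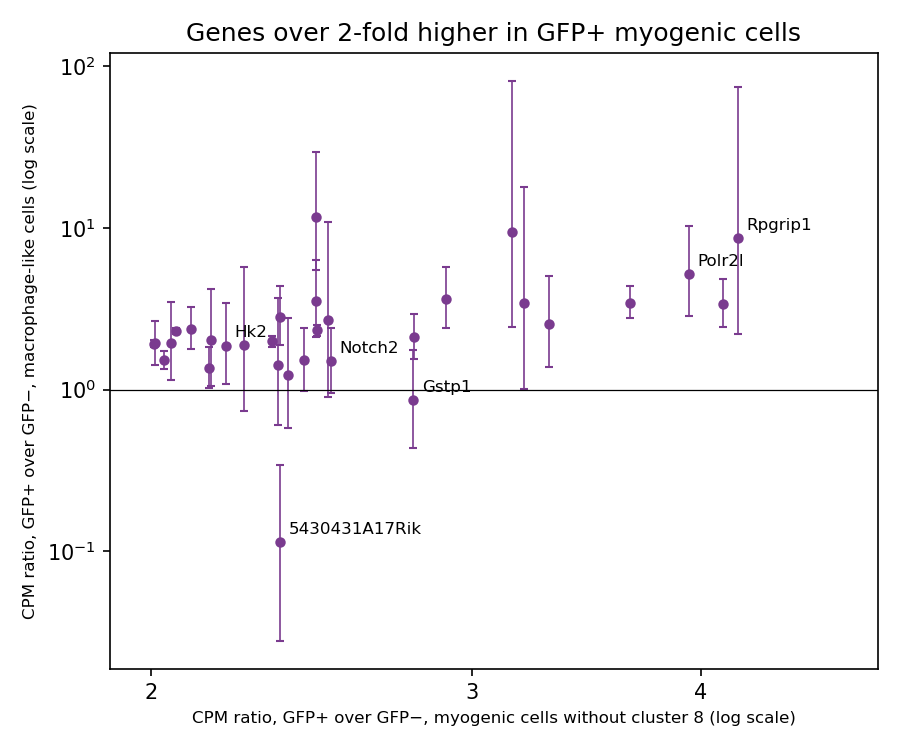
CPM ratio of GFP+ over GFP− in macrophage-like cells (vertical, log scale) against the ratio in myogenic cells without cluster 8 (horizontal, log scale) for the 31 features at least 2-fold higher in GFP+ myogenic cells that were measured in macrophage-like cells; points are ratios and bars are exact 95% counting intervals. In macrophage-like cells 29 of the 31 lie above 1.

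Gene lists fixed before the data were examined were compared by the median log2 ratio of their members, with the percentile of that median among 10000 random lists of matched expression. The shift over all genes was −0.090. The satellite cell quiescence list had a median of 0.58 (12 genes measured, interval over genes 0.18 to 0.81, percentile 100), with 6 genes at least 1.5-fold higher and 0 lower. Chodl, Gas1 and Sdc4 were at 1.98-fold, 1.92-fold and 1.75-fold. Without cluster 8 they were at 1.39-fold, 1.26-fold and 1.16-fold, with 1 gene of the list left at 1.5-fold. The PAX3 target list had a median of 0.31 (9 genes, −0.11 to 0.67, percentile 99.97), with Cxcr4, a chemokine receptor, at 1.79-fold and Fgfr4 at 1.59-fold. The Notch pathway list had 0.13 (11 genes, −0.062 to 0.74, percentile 98.9), with Notch2 at 2.66-fold (1.49-fold in macrophage-like cells, 0.951 to 2.41) and Jag1 at 1.67-fold, and the immediate-early and dissociation stress list 0.75 (19 genes, 0.43 to 0.90, percentile 100), with Nr4a1 at 3.02-fold and Jund at 2.33-fold. Nr4a1 was below its empty-droplet level in both libraries (53.7 against 88.7 CPM in GFP+), and without cluster 8 Jund was at 1.68-fold. Lists that were lower in GFP+ cells included the G2/M phase list (−0.54, 43 genes, −0.63 to −0.42, percentile 0), the S phase list (−0.29, 34 genes, −0.44 to −0.15, percentile 0; 2 genes at least 1.5-fold lower and 1 higher, Ccne2, a cyclin, at 2.36-fold), the contractile apparatus list (−0.64, 20 genes, −0.95 to −0.29, percentile 0) and the differentiation and fusion list (−0.22, 20 genes, −0.34 to −0.10, percentile 0.51). In the contractile list 10 genes were at least 1.5-fold lower and 0 higher, Myh3 at 0.503-fold and Ckm at 0.465-fold among them. Empty droplets held more of both (127 CPM of Myh3 in GFP− against 54.1 in the cells, and 62.2 of Ckm in GFP+ against 8.12). Cluster 9, which contractile genes such as Myh3 lead, had only 15 GFP+ cells against 107 GFP− cells. The Pax-Six-Eya list had a median of −0.35 but a mean of 0.39, because Pax3, the gene of the sort, and Six2 were far above the other 5 measured members. Without cluster 8 the quiescence median was 0.22, the stress median 0.33, and the Notch (0.038) and differentiation and fusion medians (−0.13) lay inside the range of random lists. With at most 5% mitochondrial UMIs per cell the G2/M median was −0.87 and the differentiation and fusion median −0.062.

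**Figure D4:**
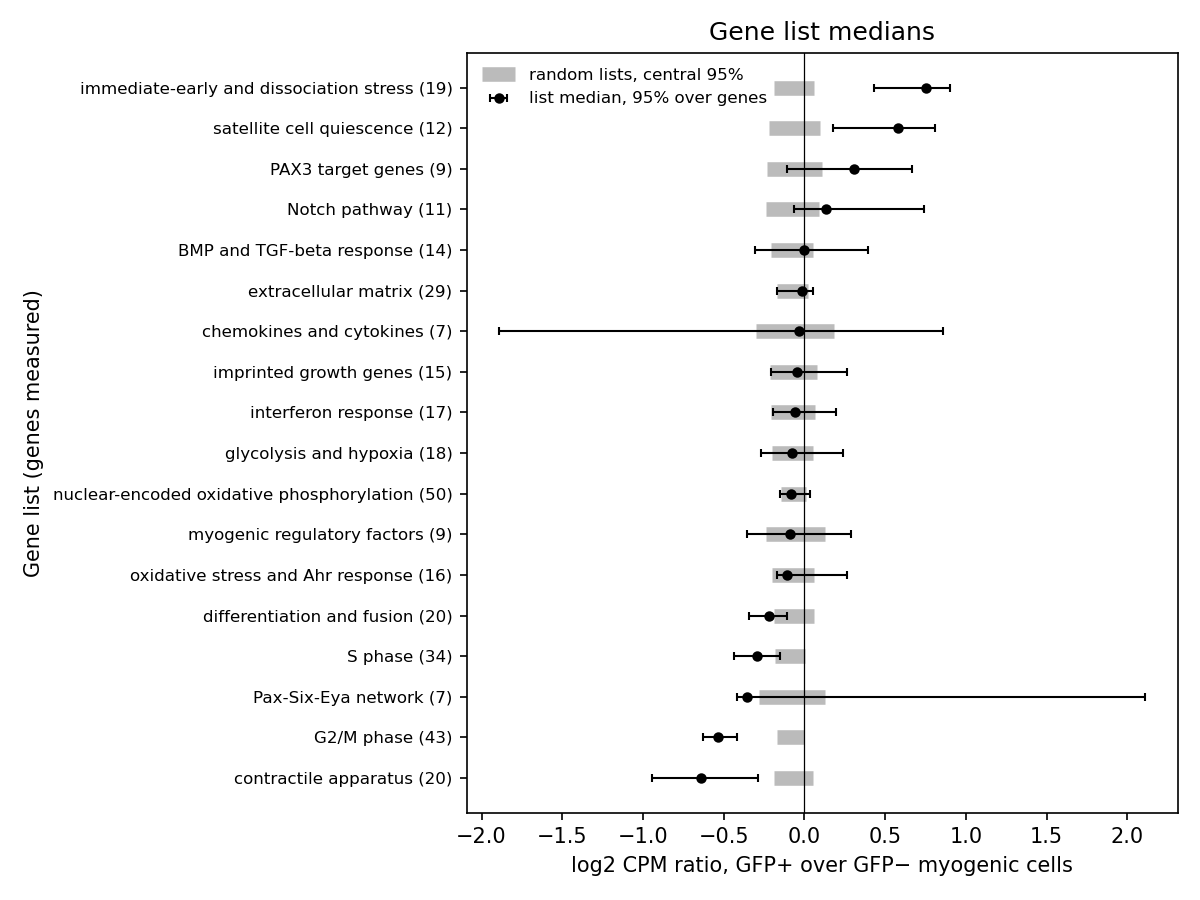
Median log2 CPM ratio of GFP+ over GFP− myogenic cells for the gene lists with enough measured genes; points are list medians with 95% intervals over genes, and grey bands hold the central 95% of matched random lists. The immediate-early and quiescence lists lie above the bands (0.75 and 0.58), and the contractile apparatus and G2/M lists lie below them (−0.64 and −0.54).

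A further 11 lists had medians inside the central 95% of random lists. These were the myogenic regulatory factors (−0.090), extracellular matrix (−0.014), interferon response (−0.059), chemokines and cytokines (−0.036), glycolysis and hypoxia (−0.074), nuclear-encoded oxidative phosphorylation (−0.081), oxidative stress and Ahr response (−0.10), BMP and TGF-beta response (−0.0037), imprinted growth genes (−0.048) and, with 3 measured genes each, Wnt response (0.16) and the 5-prime Hoxa and Hoxd genes (0.019). The mean had the other sign than the median for glycolysis and hypoxia (0.030), BMP and TGF-beta response (0.087), imprinted growth genes (0.099) and the 5-prime Hox genes (−0.019). The interferon and chemokine lists held Cxcl10 and Il33, an alarmin cytokine, at 0.176-fold and 0.270-fold, and without cluster 8 the chemokine median was −0.36 over 6 genes, at percentile 0.51. Fn1, an adhesive matrix glycoprotein, was at 0.550-fold (0.525 to 0.577). Hk2, a hexokinase of glycolysis, was 2.39-fold higher (2.13 to 2.68), and 1.87-fold higher in macrophage-like cells (1.07 to 3.42).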

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

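A signal stood outside the planned comparisons: the reporter feature, whose name joins a histone-GFP fusion to TVA and B19G, is no mouse gene. It carried 567 UMIs in GFP+ myogenic cells and 0 in GFP− myogenic cells. Because the cells were sorted on GFP, the sort would give this contrast if the counted sequence covers that GFP. Whether it does is not given in the sources used here. In the GFP+ library the feature was also at 0 UMIs in the macrophage-like cluster, where 64.3 would be seen at the myogenic level. The same held in the mural-like cluster, where 11.2 would be seen. No explanation was tested for the feature.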

How the results depend on the processing

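In all, 497 summary values were recomputed under 23 settings: 459 stayed within the interval of the reported value or, for counts of genes, within 1.5 times, and 38 moved. Of 1870 single-gene values, 229 moved and 10 changed sign. A change of sign was counted only where the interval of the reported value excluded no difference, and 0 of the 497 summary values changed sign by this rule; list medians near 0 and ratios near 1 crossed it without being counted. Pax3 ranged from 3.33 to 6.12-fold and Six2 from 2.57 to 3.20-fold. The settings without cluster 8, with high doublet scores removed, with stress genes or genes over 1.5-fold apart left out of clustering, and with the length trend removed were chosen after seeing the data. No paired analysis was possible because each group has 1 library.

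Without cluster 8, Pax3 was at 3.40-fold, 38 genes were at least 2-fold higher, the stress list was at 0.33, and Srxn1 (0.821), Tiparp (0.991), Wnt4 (0.933) and Meg3 (0.829) turned below 1; here the removed cells are the cause by construction. With genes over 1.5-fold apart left out of clustering, the cluster matching cluster 8 was classed as endothelial and left the myogenic class: the myogenic shares were 66.6% and 90.6%, Pax3 was at 3.33-fold, 39 genes were higher, the stress list was at 0.31, and Srxn1 (0.839), Tiparp (0.995), Wnt4 (0.900) and Meg3 (0.811) turned below 1. With cells weighted equally, Pax3 was at 6.12-fold, Six2 at 2.57-fold, 180 genes were higher, and the quiescence, stress and oxidative phosphorylation lists were at 0.99, 1.19 and −0.19; the cause was not tested. Over all kept cells, 216 genes were higher and 33 lower, the interferon list was at 0.27 and Gpx1 turned from 0.775 to 1.22; this setting adds the non-myogenic cells. With at most 5% mitochondrial UMIs, 29 genes were lower, the differentiation and fusion, S and G2/M lists were at −0.062, −0.44 and −0.87, the GFP− share with 3 G2/M UMIs was 82.2% and Pgam2 turned from 0.718 to 1.09; the cause was not tested. With order-of-magnitude cell calling, the GFP− myogenic share was 93.8% and cluster 8 held 0.923% of GFP− myogenic cells, with a UMI minimum of 3812 there, above that cluster's median depth of 3592.

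A minimum of 5 CPM gave 152 higher and 39 lower genes and one of 50 CPM gave 43 and 4, by construction. Shares follow depth by construction: Myog+ cells were 24.3% (GFP+) and 29.2% (GFP−) without thinning and 12.7% and 15.9% at 1000 UMIs, and cells with 3 G2/M UMIs were 91.9% and 96.0%, and 14.1% and 21.6%. A minimum of 5 G2/M UMIs gave 44.0% and 53.1%. The GFP+ share stayed below the GFP− share in each of these. Pax3 and Six2 rested on 217 and 339 UMIs in GFP− myogenic cells.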

Other observations

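Pax3 and Six2 differed in where they were highest. Within the GFP+ library Pax3 ranged from 82.2 CPM in cluster 8 (63.1 to 105) and 38.4 in cluster 2 to 14.0 in the Spp1 and Fn1 cluster 0 and 9.51 in the cycling-like cluster 4, whereas Six2 stood at 37.7 CPM in cluster 0 (30.4 to 46.3) and at 11.9 in cluster 8 (5.46 to 22.7) and 6.98 in the Myog and Mymk cluster 5. At 5000 UMIs, 3 of 459 GFP+ cells held both transcripts where independence gives 6.83, and 8 of 2345 GFP− cells did where it gives 2.77. Cxcl10, an interferon-induced chemokine, was above its empty-droplet level (37.2 CPM in GFP+ and 67.2 in GFP−) in 1 myogenic cluster, the interferon cluster 3, where it was lower in GFP+ cells (52 against 1697 UMIs, 0.121-fold). It was lower also in the macrophage-like (0.518, 0.436 to 0.616) and mural-like clusters (0.269, 0.146 to 0.459). The GFP+ mural-like value rests on 6 cells. Des there was at 4.85 CPM against 436 in GFP−, so these cells may not be alike. The positional gene Hoxc10 was at 0.721-fold (0.642 to 0.808) and Hoxc11 at 0.616-fold (0.483 to 0.776) in GFP+ myogenic cells, with a hindlimb list median of −0.48 over 4 genes (percentile 0.060 among random lists); Hoxc6, the measured member of the forelimb list, had a log2 ratio of −0.25. Since it is not given which muscles entered each library, a difference in muscle of origin was not tested. The hindlimb gene Tbx4, too low for the list median, was at 6.40 and 6.36 CPM (1.01-fold, 0.758 to 1.32), and Tbx5 and Pitx1 had 0 UMIs in both. The list of X-inactivation and Y-linked genes had a median of 0.073 and a mean of −0.050, with Ddx3y at 63.1 and 64.5 CPM and Xist at 0 and 4 UMIs. Macrophage-like cells were 5.89 times as frequent in the GFP+ library (4.12 to 8.46) and mural-like cells 0.213 times (0.077 to 0.477).

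The tests on Six2 and the test of the length trend as the whole cause were chosen only after the results were seen. The larger cluster 8 share in GFP+ was set against depth, stress genes and genes that differ between the libraries. Among myogenic cells of 1000 to 10000 UMIs the cluster held 74.3% of GFP+ (66.2 to 81.3) and 10.6% of GFP− cells (7.95 to 13.9), a ratio of 6.98. GFP+ myogenic cells were deeper as a whole (median 19114 against 14996 UMIs), which argues against fewer UMIs per cell in that library as the cause. Depth was not matched inside the window and cluster 8 is itself low in depth, so a part played by depth or cell quality cannot be told apart. With stress genes left out of clustering the ratio was 12.2, and with the genes over 1.5-fold apart left out it was 9.85. Neither group of genes was thus needed for the cluster to form. Genes that vary with them may have stayed among the features, so a stress state of these cells cannot be told apart. With the genes over 1.5-fold apart left out, the matching cluster was classed as endothelial. In the main clustering, however, cluster 8 held Pax7 at 637 CPM in GFP+ and 591 in GFP− cells, and Myf5 at 525 and 269. These values argue against endothelial cells, but whether cluster 8 is quiescent satellite cells stays open. A larger quiescent-like fraction among PAX3+ cells remains as an untested hypothesis, and a difference in handling between 2 unreplicated libraries, which was not tested, stays open.

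Outside cluster 8, 38 features were at least 2-fold higher in GFP+ myogenic cells, among them the reporter feature, mt-Atp8, Rps28, Rps29 and Six2. Across 7721 genes in myogenic cells and 7413 in macrophage-like cells, which are not independent replicates, transcript length and log2 ratio had Spearman correlations of −0.174 and −0.158, so a length trend as a part of the difference cannot be told apart from others. Removing the trend left 32 of the 38 features in the set, and 30 of the 36 whose known length let the removal act on them, which argues against it as the whole cause. In macrophage-like cells the 31 features measured had a median log2 ratio of 1.07 (lower limit 0.91), and 29 of them were higher in GFP+, against a median of −0.19 over all genes there, consistent with a library-wide difference not tied to the cell type; what lies behind it was not tested, and an effect of the sort on all cells stays open.

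Six2 was weighed because it could share either of these origins. It was lower in GFP+ cluster 8 (11.9 CPM, 5.46 to 22.7) than over all GFP+ myogenic cells (24.4 CPM), so the larger share of that cluster did not raise its ratio. For the same reason its ratio without cluster 8, with a lower limit of 2.67, was bound to stay high and is no separate test. The second quiescent-like cluster 2 was not left out. Whether a library-wide difference contributes cannot be told apart: the mural-like cluster gave a ratio of 1.04 (0.023 to 8.54) from 1 and 6 UMIs, too few to decide. A tie of Six2 to the PAX3+ state, which the design names, stays open and was not tested against replicates.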
